A study of Nannochloropsis oceanica with 6 samples.

How the data were processed

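RNA was sequenced from 6 cultures of Nannochloropsis oceanica IMET1, 3 under nitrogen deprivation (ND) and 3 under nitrogen repletion (NR). Per the labels' protocols, total RNA was extracted with Trizol and libraries followed standard Illumina protocols. The submitters' processing notes name Trim Galore, STAR, Picard, featureCounts, StringTie and edgeR, with no versions and no roles. The genome build and the tool that made the estimated counts are not given in the sources used here.

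Each library has a deposited table of 10481 genes, 148 of them with names that mark models added to the annotation. The authors deposited an estimated count (expected count) per gene, per the file headers, without normalisation, and 79.6% to 80.9% of the genes had whole values in a library. TPM values in the deposited tables, per the file headers, sum to a fixed total in each library. FPKM values in the deposited tables, per the file headers, are scaled to effective length and library total. The authors also deposited a comparison of ND with NR that lists a log2 fold change, a p-value and an FDR for 2057 genes, all with an absolute log2 change above 1 and an FDR under 0.05, and its FPKM values equal those of the library tables. Gene names and descriptions came from the deposited annotation, which describes 7137 genes. The reference table given for the organism holds 160 genes and matched 0 of the gene IDs, so no coordinates are reported. No column of per-sample values was left unassigned to a library.

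Library totals ran from 3972986 to 5693513 estimated counts, a ratio of 1.43. Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, trimmed mean of M-values, quasi-likelihood F test), ND against NR, with no block for replicate number and Benjamini-Hochberg adjustment at 0.05. The standard error of a log2 fold change is its absolute value over the square root of F. A gene with no count in a group was set against a floor of 3 counts over that group, and a gene with 1 to 3 counts has an exact binomial (Clopper-Pearson) interval at 95%; these cover counting error only. The scaling factors were 0.89, 0.89 and 0.908 in NR cultures and 1.111, 1.114 and 1.123 in ND cultures, and the biological coefficient of variation was 0.0475. Pairs of libraries of a condition differed by more than counting error, with chi-square per degree of freedom of 1.73 to 2.98 over genes with at least 20 counts, so no library duplicates another.

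The 25 gene lists were matched to the names and descriptions in the annotation. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01 on log2 CPM with a prior count of 2, with members also adjusted over the list alone. The lists cover fatty acid synthesis, triacylglycerol assembly, desaturases and elongases, lipases and beta-oxidation, membrane glycerolipids, nitrogen uptake, light harvesting, chlorophyll, carotenoids, the Calvin cycle, glycolysis, lactate and methylglyoxal, the citrate and glyoxylate cycles, ribosomal proteins, ribosome biogenesis, translation factors, the proteasome and autophagy, histones, DNA replication, storage and wall carbohydrates, redox and heat-shock proteins, phosphate and sulfur uptake, transcription factors, organelle genes, and transposable elements. Of 9 lists called at the preset correlation, light harvesting and ribosome biogenesis held with an estimated correlation. The main test, the lists, the alternatives listed first below and the rule for named genes were fixed before the data were examined.

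By that rule the text names 3 kinds of genes. The first are the 8 largest rises and 8 largest falls by fitted log2 fold change among genes with an adjusted p under 0.05, a mean of at least 10 CPM in the higher group, non-overlapping libraries and a name or description other than hypothetical, uncharacterized, unknown, unnamed or predicted protein. The second are the 3 members of each list with the smallest p-values, and the third the 5 genes with the highest mean TPM in each condition. Other named genes were chosen after their values were seen, and the text says so. Some genes that the rule picks are not reported.

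The alternatives fixed in advance were a replicate block, RLE and upper-quartile factors, DESeq2 1.42.0, limma with trend on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with FPKM of at least 1 in 3 libraries, no filter, at least 10 CPM in 3 libraries, an adjusted p of 0.01, a test against a change of 1.5 times, each library left out, and, for lists, an estimated correlation and fry. Added after seeing the data were thinning to equal depth, library totals alone, genes with whole counts only, lists matched on the displayed description only, and the KEGG pathways of the deposited annotation with at least 10 tested members. The deposited lengths, which are averages over transcripts weighted by abundance, were compared with limma on the log2 scale in genes with more than 1 transcript and at least 50 counts in every library.

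The methods were tested on simulated counts for 9329 genes. The all-gene test recovered 76.1% of 67 genes changed 1.5 times, 88.1% of 67 changed 2 times and 98.5% of 66 changed 4 times, and called 5 of 9129 unchanged genes. Of 100 random lists 7 had a camera p under 0.05, and a list of 50 genes raised 1.3 times was called. The simulated genes varied independently of one another and few of them were changed, unlike the real data. The simulation therefore tests neither the effect of correlation between genes nor the scaling between libraries. The length comparison recovered 45 of 50 simulated shifts and called 4 of 3076 unshifted genes.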

Results

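The data are RNA sequencing profiles of Nannochloropsis oceanica IMET1, a unicellular marine alga that accumulates oil. Cells in logarithmic growth were washed and transferred either to complete f/2 medium (nitrogen repletion, NR) or to the same medium without nitrogen (nitrogen deprivation, ND), with 3 separate cultures per condition, and were collected after 72 h. The comparison asks which transcripts differ between nitrogen-deprived and nitrogen-fed cells, in a study concerned with the control of lipid production. Estimated counts summed to 4563940, 4086489 and 3972986 in NR cultures 1 to 3 and to 4383211, 4976087 and 5693513 in ND cultures 1 to 3. With these totals, 3 counts over the 3 libraries of a group corresponded to 0.265 CPM (counts scaled by library total) in NR and 0.179 CPM in ND, a floor that covers counting error only. Libraries of the same condition were correlated at r = 0.984 to 0.991 across genes, against 0.839 to 0.846 between conditions. The first principal component, which separated the conditions, held 89.3% of the variance. The libraries also differed by condition in composition, since the 100 most abundant genes held 25.18% to 25.53% of all TPM (length-scaled transcript abundance) in NR and 18.33% to 18.59% in ND. The gap between gene length and the deposited effective length, which follows the fragment size, was 249.4 to 255.2 bp in NR and 266.8 to 271.6 bp in ND. Where the estimated counts of a gene were not all whole, part of its reads was divided with another gene model. Such genes are marked with the words shared reads, and their values are uncertain. Models are called adjacent by the order of their gene IDs, as no coordinates were available. Unless stated otherwise, levels are mean ± SD in normalised CPM with n = 3, and changes are log2 fold changes of ND over NR ± SE.

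After 72 h without nitrogen, the transcripts of light-harvesting proteins, fatty acid synthesis, carbon fixation and wall carbohydrates were lower, and those of nitrogen uptake, ribosome assembly and ribosomal proteins were higher. With an estimated correlation between genes only light harvesting and ribosome assembly were still called (camera adjusted p = 0.0201 for both), and the other lists had adjusted p-values of 0.278 to 0.45. Of 9329 genes tested, 6645 (71.2%) differed at an adjusted p of 0.05 in edgeR's quasi-likelihood test, 3333 higher and 3312 lower in ND. A change of at least 2 times was found for 2044 of them, 876 higher and 1168 lower. At 4 times or more, falls outnumbered rises, with 453 genes lower and 137 higher (347 and 235 with library totals alone). At 2 times or more the order depended on the scaling, with 1097 genes higher and 1025 lower under upper-quartile factors and 1658 higher and 814 lower with library totals alone. The balance between rises and falls depended on the scaling between libraries. With library totals alone, the median change of all genes moved from 0.02 to 0.34 and 5075 of 7224 called genes (70.3%) were higher in ND. With limma on log2(FPKM + 1) the median was 0.34 and 5090 of 7121 (71.5%) were higher. The changes given here are relative to the typical gene under the trimmed mean scaling.

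**Figure D1:**
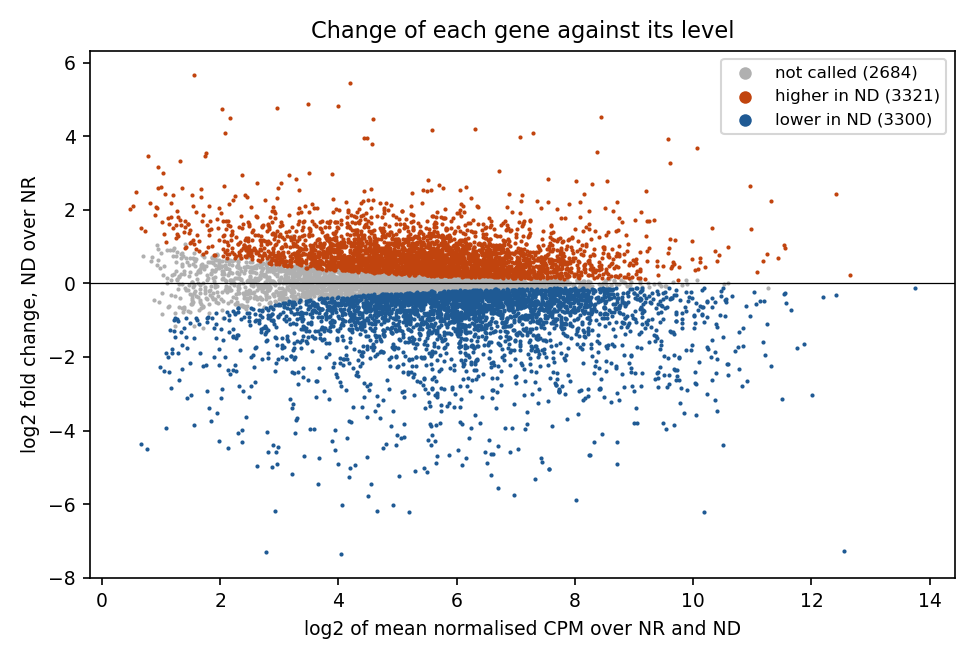
Each point is a gene with counts in both conditions, with the log2 of its mean normalised CPM over NR and ND on the x axis and its log2 fold change (ND over NR) on the y axis. Orange points passed an adjusted p of 0.05 as higher in ND, blue points as lower, and grey points did not pass; genes at 0 in one condition are left out.

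Light-harvesting and photosystem genes showed the largest shift of any list. Of 48 tested members 40 fell, 1 rose and 7 did not pass the test, with 41 passing when adjusted over the list alone and a median change of -1.83. FCPA (NO25G00860), annotated as a fucoxanthin-chlorophyll a-c binding protein, dropped from 11910 ± 575 to 77.5 ± 8.54 CPM, a change of -7.27 ± 0.07, with shared reads. Another antenna gene, NO24G02290, went from 815 ± 38.7 to 27.1 ± 1.25 CPM (-4.91 ± 0.07). The level of CAB6A (NO21G02150), annotated as a chlorophyll a-b binding protein, went from 799 ± 20.9 to 40.4 ± 2.81 CPM (-4.31 ± 0.06). The only member that rose, against 6 with library totals alone, was an LHCSR1 gene (NO18G00330, +1.16 ± 0.04), chosen after its values were seen. Another LHCSR1 (NO02G05990), a stress-related antenna protein and the more abundant one in NR, fell from 1899 ± 43.0 to 659 ± 12.9 CPM. The level of NO18G00330 went from 622 ± 23.3 to 1392 ± 6.02 CPM. CPM is not scaled for gene length, so these values do not show which of the genes was the more abundant in ND. The list was lower as a set (camera adjusted p = 2.83e-15), and adjusted p = 0.0201 with an estimated correlation.

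Among chlorophyll and tetrapyrrole synthesis genes 14 of 26 fell and 8 rose (22 adjusted over the list alone). They were led by CAO (NO16G01210, -2.03 ± 0.06), annotated as a chlorophyllide a oxygenase, the glutamyl-tRNA reductase hemA (NO09G01210, -1.75 ± 0.05) and the magnesium chelatase subunit CHLH (NO22G01810, -1.57 ± 0.05). For carotenoid and isoprenoid synthesis 30 of 63 fell and 18 rose (50 adjusted over the list alone). The hydroxymethylglutaryl-CoA synthase hgsA (NO08G03590, -2.80 ± 0.06), GGPS1 (NO04G03790, -1.76 ± 0.06) and the phytoene desaturase PDS1 (NO16G01970, -1.28 ± 0.05, shared reads) had the smallest p-values. Neither list differed as a set (camera adjusted p = 0.123 for both), and their medians of -0.32 and -0.13 became -0.01 and 0.18 with library totals alone. Of 26 Calvin cycle and carbon concentration genes 20 fell and 5 rose, and 25 passed when adjusted over the list alone. The median was -0.65, and -0.34 with library totals alone (16 lower and 6 higher). The carbonic anhydrase cah-3 (NO20G00630) fell from 534 ± 35.2 to 63.6 ± 2.71 CPM (-3.07 ± 0.06) and the ribose-5-phosphate isomerase RPI3 (NO08G03720) changed by -1.56 ± 0.07. The member that rose most clearly, SLC38A11 (NO09G03420, +1.62 ± 0.08, shared reads), is annotated as an amino acid transporter and not as an enzyme of carbon fixation. The set was lower (camera adjusted p = 0.00229), with adjusted p = 0.45 with an estimated correlation.

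Nitrogen uptake and assimilation genes were higher as a set. Of 87 tested members 43 rose and 28 fell, and 71 passed when adjusted over the list alone. The median change was 0.24 (camera adjusted p = 0.015; adjusted p = 0.278 with an estimated correlation and 0.104 with whole counts only). With library totals alone it was 0.56, with 55 members higher and 14 lower. The nitrate reductase NIA (NO14G02460) rose from 29.1 ± 4.17 to 665 ± 7.50 CPM, 22.9 times. NRT2.1 (NO14G02450), a high-affinity nitrate transporter, rose 15.2 times to 1433 ± 30.3 CPM, with shared reads. The Rh-type ammonium transporter rhbg (NO30G00980) rose 6.85 times to 651 ± 19.0 CPM. The gene nrgA (NO09G03110), an ammonium transporter among the most abundant transcripts of deprived cells, rose 2.07 times to 4007 ± 83.4 CPM. Further members picked after their values were seen included the nitrite reductase nirA (NO26G00710, +1.50 ± 0.04), urease (NO02G06110, +2.05 ± 0.06, shared reads), an NADH-dependent glutamate synthase (NO08G04050, +1.48 ± 0.05, shared reads) and the glutamine synthetase GLN1-2 (NO07G03230, +0.80 ± 0.04). Another putative ammonium transporter (NO20G02430) fell by 1.88 on the log2 scale.

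**Figure D2:**
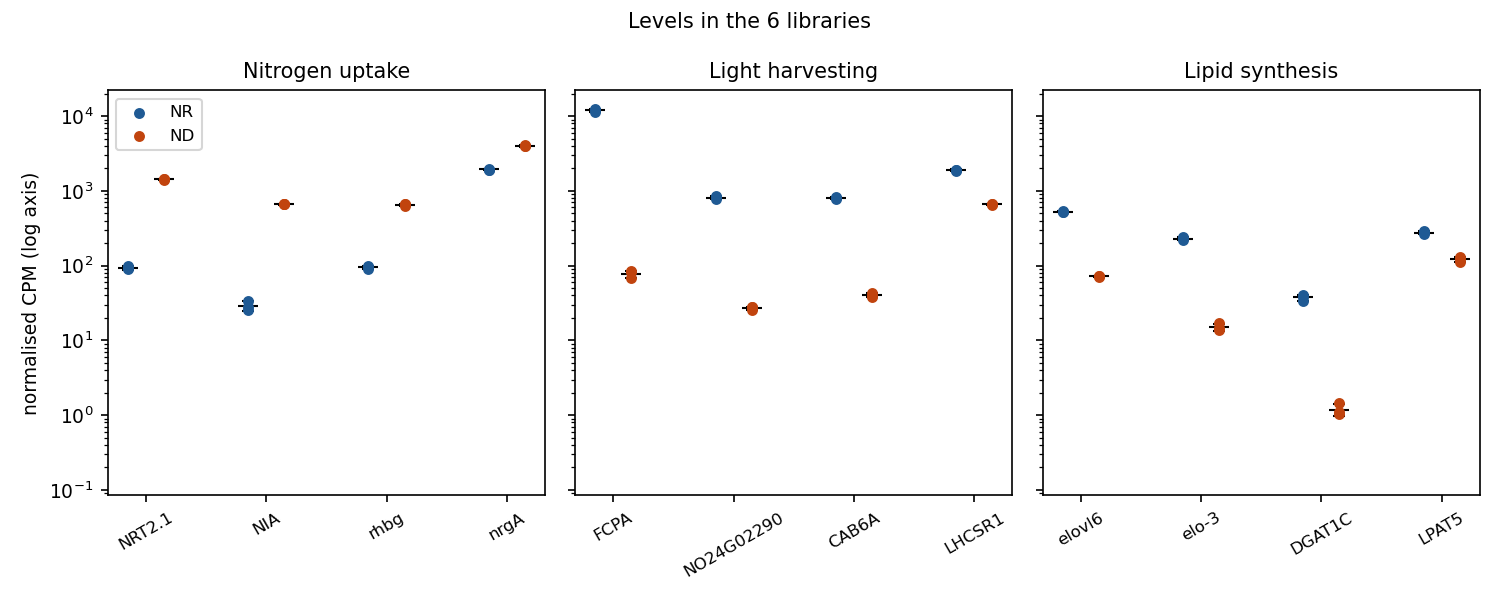
Normalised CPM on a log axis of 12 genes of nitrogen uptake, light harvesting and lipid synthesis, with each point a library and bars giving the mean ± SD of the 3 NR (blue) or 3 ND (orange) libraries. In all 12 genes the libraries of the conditions do not overlap, with the nitrogen uptake genes higher and the others lower in ND. The genes are among those that the rule names, most of them for small p-values, which favours libraries that do not overlap. Lipid genes that rose, such as LPAT2, DGAT1B and DES6, are not shown.

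Fatty acid synthesis genes were mostly lower in ND. Of 37 tested members 26 fell and 6 rose, and 32 passed when adjusted over the list alone. The median change was -0.54 (camera adjusted p = 0.000457; adjusted p = 0.278 with an estimated correlation). With library totals alone it was -0.22, with 20 members lower and 10 higher. The members with the smallest p-values were annotated as polyketide synthases, enzymes that share domains with fatty acid synthases: pytA (NO06G02810, -2.88 ± 0.06), hpm8 (NO01G02200, -2.14 ± 0.06) and swnK (NO11G02690, -1.59 ± 0.05). Among the core enzymes, chosen after their values were seen, the acetyl-CoA carboxylase ACAC (NO09G00220) fell from 2578 ± 180 to 1112 ± 25.4 CPM (-1.21 ± 0.05). The acyl carrier protein acpP (NO30G00840, -1.07 ± 0.05), fabD (NO07G02760, -1.21 ± 0.08), fabH (NO28G00420, -1.66 ± 0.14) and fabF (NO28G00410, -0.94 ± 0.05) fell with it. Desaturases and elongases moved both ways, with 16 of 31 lower and 8 higher (24 adjusted over the list alone; camera adjusted p = 0.0962). Their median was -0.25 and became 0.06 with library totals alone. The elongases elovl6 (NO29G00510) and elo-3 (NO12G02800) fell from 528 ± 11.6 to 71.9 ± 0.38 CPM and from 231 ± 9.41 to 15.2 ± 1.59 CPM, and the desaturase D4 (NO01G04670) changed by -2.21 ± 0.07. In contrast, DES6 (NO28G00700, +2.02 ± 0.10, shared reads) and a delta-12 desaturase (NO11G02480, +1.49 ± 0.07), both singled out after seeing the values, rose.

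Genes of triacylglycerol assembly, the pathway that makes storage oil, divided almost evenly. Of 34 tested members 15 rose, 13 fell and 6 did not pass, and 29 passed when adjusted over the list alone. The set test found no shift (camera adjusted p = 0.823). The list's median was 0.01 (0.33 with library totals alone, with 19 higher and 8 lower). Its mean of -0.36 differed in sign and rested largely on LPAT4, which had no count in ND, and was -0.06 without it. The diacylglycerol acyltransferase DGAT1C (NO14G03060) fell from 37.6 ± 3.39 to 1.19 ± 0.22 CPM, 30.9 times. The level of LPAT5 (NO01G00580, shared reads), an acyltransferase making phosphatidic acid, changed by -1.20 ± 0.06. LPAT4 (NO12G03190) had 35.1 ± 1.53 CPM in NR and no count in ND, at least 197-fold lower against a floor of 3 counts over the group. Its reads were divided with the adjacent LPAT4 model NO12G03180, and the sum of both changed by -0.97 ± 0.06. Rises in this list included LPAT2 (NO12G00800, +1.27 ± 0.07, shared reads) and the diacylglycerol acyltransferases DGAT1B (NO19G00260, +0.65 ± 0.07) and DGAT2D (NO07G01760, +0.73 ± 0.10, shared reads), picked after their values were seen. Membrane glycerolipid synthesis was lower, with 17 of 30 members falling and 6 rising (23 adjusted over the list alone; camera adjusted p = 0.032; adjusted p = 0.278 with an estimated correlation). The adjusted p was 0.127 with whole counts only and 0.0643 on the displayed description, and the median of -0.27 became 0.05 with library totals alone. It was led by SQD1 (NO07G01150, -1.54 ± 0.06) and SQD2 (NO15G02830, -2.99 ± 0.12), which make the chloroplast sulfolipid. Lipase and beta-oxidation genes showed no shift as a set (45 of 125 rose and 42 fell, or 75 and 30 with library totals alone, 87 adjusted over the list alone, camera adjusted p = 0.998). Their median of 0.03 and mean of -0.12 differed in sign. The putative long-chain acyl-CoA ligase HI_0002 (NO25G00730) fell from 508 ± 18.7 to 8.75 ± 2.02 CPM. The protein sym-1 (NO05G03010) also fell (-2.35 ± 0.05), as did a PXMP2/4 family protein (NO04G02750), from 1385 ± 26.6 to 348 ± 12.8 CPM. The displayed description of neither names a lipase or an enzyme of beta-oxidation.

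Storage and wall carbohydrate genes fell in 35 of 55 cases and rose in 11 (46 adjusted over the list alone), and the median was -0.56 (camera adjusted p = 0.000288; adjusted p = 0.278 with an estimated correlation). With library totals alone it was -0.24, with 30 members lower and 20 higher. The cellulose synthase bcsAI (NO07G03720) fell from 952 ± 21.9 to 69.3 ± 4.92 CPM. The gene dcsA (NO28G00320, shared reads), also annotated as a cellulose synthase, changed by -3.94 ± 0.09. The other of the 3 members with the smallest p-values was again the polyketide synthase pytA. In glycolysis and pyruvate metabolism 34 of 76 genes rose and 26 fell (50 and 15 with library totals alone, 61 adjusted over the list alone; camera adjusted p = 0.276). Aldolases there moved apart, with FBA6 (NO19G01750) at +1.71 ± 0.05 and FBA8 (NO01G03170, shared reads) at -3.10 ± 0.11, and the chloroplast glyceraldehyde-3-phosphate dehydrogenase GAPC1 (NO27G00910) fell (-1.60 ± 0.05). The citrate and glyoxylate cycle list had 20 of 36 members higher and 11 lower (31 adjusted over the list alone; camera adjusted p = 0.118, and 0.0149 with whole counts only). On library totals alone 24 were higher and 9 lower. It showed rises of SDH1 (NO01G01530, +1.43 ± 0.05) and scsC (NO24G00360, +1.28 ± 0.05), subunits of succinate dehydrogenase and succinate-CoA ligase, and a fall of the ATP-citrate synthase ACLY (NO01G01420, -1.01 ± 0.05), which supplies cytosolic acetyl-CoA.

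Lactate and methylglyoxal genes bear on the lactylation named in the study's title. Of 11 tested members 3 rose, 3 fell and 5 did not pass (7 rose and 2 fell with library totals alone; 5 adjusted over the list alone; camera adjusted p = 0.983). The median of 0.03 and mean of -0.15 differed in sign. The mitochondrial D-lactate dehydrogenase DLD (NO16G02360) fell from 177 ± 9.96 to 73.6 ± 1.41 CPM (-1.26 ± 0.07). The other members with small p-values, Bamb_3547 (NO09G01600, -1.46 ± 0.11), annotated as a pyrroline-carboxylate reductase, and ADE17 (NO07G01560, +0.58 ± 0.05), of purine synthesis, are not enzymes of lactate. Chosen after their values were seen, the glyoxalases GLO1 (NO20G00020, +0.17 ± 0.08, shared reads, edgeR adjusted p = 0.048) and glod-4 (NO03G04960, -0.25 ± 0.05) showed small changes. GLO1 lost its call with RLE factors and with DESeq2. The sign of glod-4 reversed with library totals alone and in both FPKM fits.

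Most transcripts for making ribosomes were higher. Of 123 ribosome biogenesis and RNA polymerase I and III genes 87 rose and 13 fell (101 adjusted over the list alone), and the median was 0.54 (0.85 with library totals alone). The set was higher (camera adjusted p = 5e-08), with adjusted p = 0.0201 with an estimated correlation. HEATR1 (NO20G00480), a factor of rRNA production, rose from 70.2 ± 2.27 to 232 ± 12.5 CPM (+1.72 ± 0.07) and the RNA methyltransferase NSUN2 (NO06G00650) rose by 2.08 ± 0.09. In contrast, MAF1 (NO27G01570), a repressor of RNA polymerase III, fell (-1.39 ± 0.05). Ribosomal protein genes rose in 64 of 100 cases and fell in 12 (76 adjusted over the list alone), with a median of 0.34, or 0.66 with library totals alone (camera adjusted p = 2.23e-05; adjusted p = 0.348 with an estimated correlation). RPL6 (NO25G00760) changed by +1.33 ± 0.06, RpS20 (NO08G04350) by +1.28 ± 0.07 and rps4 (NO03G04500, shared reads) by +0.94 ± 0.05. The aminoacyl-tRNA synthetase and translation factor list was also higher (60 of 116 rose, 29 fell, 89 adjusted over the list alone, median 0.26 or 0.57 with library totals alone, camera adjusted p = 0.0272; adjusted p = 0.46 with an estimated correlation). Members with small p-values that fell were Eefsec (NO02G01060, -1.37 ± 0.05, shared reads), the selenocysteine elongation factor, and the alanyl synthetase ALATS (NO08G02150, -1.05 ± 0.05, shared reads).

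**Figure D3:**
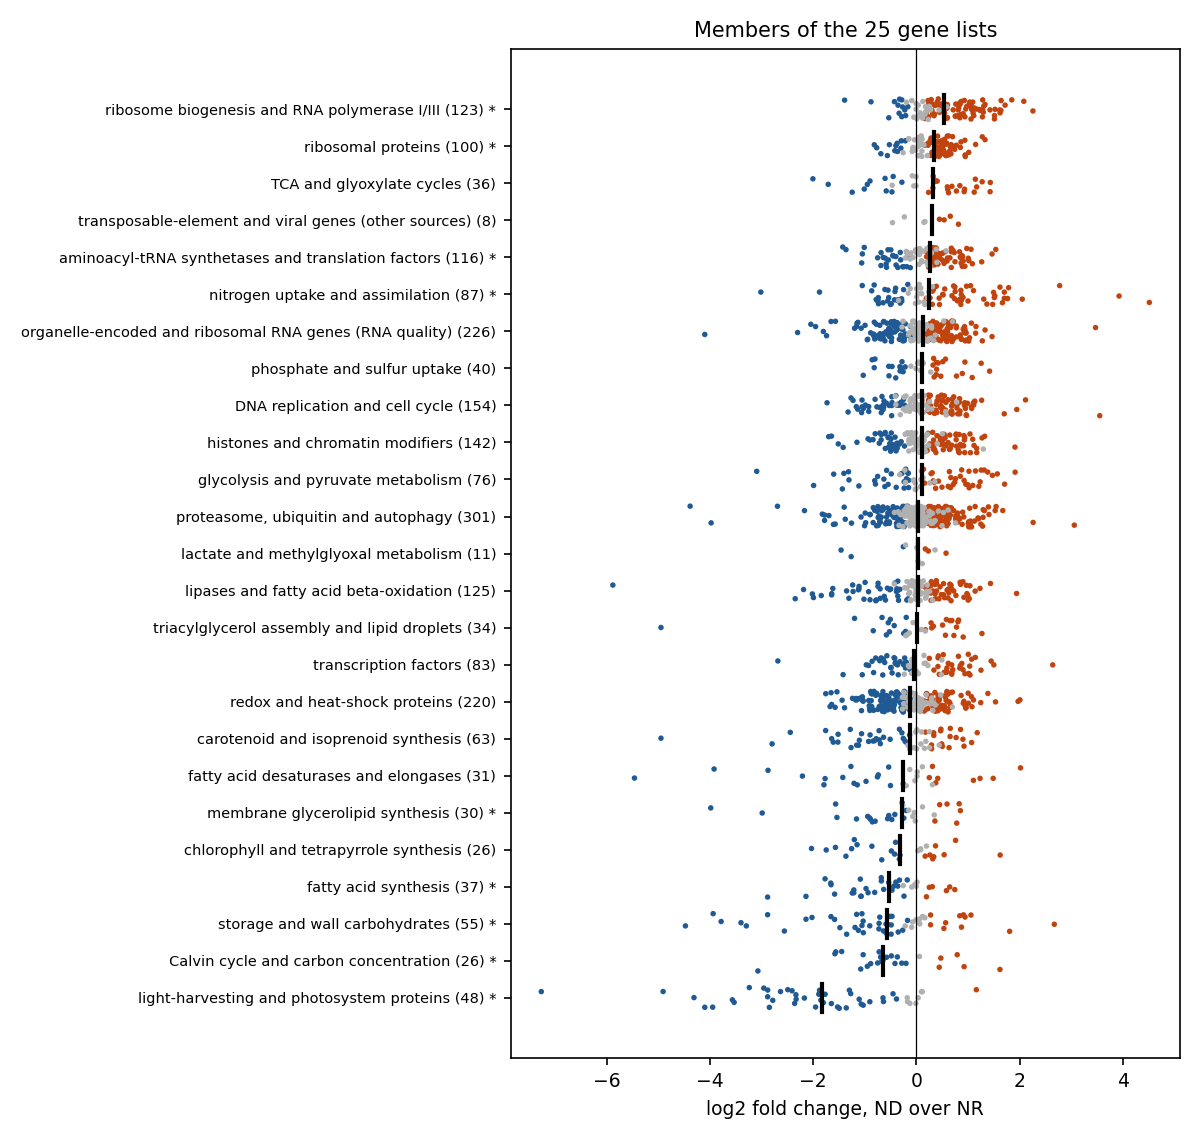
Log2 fold change (ND over NR) of every tested member of the 25 gene lists, with the number tested in brackets; orange points rose, blue points fell, grey points did not pass, black bars are medians and members at 0 in one condition are left out. An asterisk marks the 9 lists with a camera adjusted p below 0.05, from light harvesting (median -1.83) to ribosome biogenesis (median 0.54).

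Histone and chromatin genes, which bear on the epigenome named in the title, did not shift as a set (57 of 142 rose and 37 fell, or 91 and 20 with library totals alone, 94 adjusted over the list alone, camera adjusted p = 0.211). The nucleosome assembly protein NAP1;1 (NO12G03330, +1.17 ± 0.09), the remodeller Smarca1 (NO08G01460, +1.05 ± 0.08) and the cell-cycle kinase nimX (NO27G00550, +0.93 ± 0.08) rose. Members picked after their values were seen moved both ways, such as GCN5 (NO12G02280, +0.50 ± 0.06, shared reads) and HAT1 (NO22G01630, -0.68 ± 0.06, shared reads), both histone acetyltransferases, and cobB (NO27G00700, -1.15 ± 0.10), an NAD-dependent protein deacylase. DNA replication and cell cycle genes likewise showed no shift (66 of 154 rose and 39 fell, or 97 and 21 with library totals alone, 105 adjusted over the list alone, camera adjusted p = 0.211). Falls were seen for the cyclin CCNY (NO12G03480, -1.05 ± 0.04), the condensin subunit smc2 (NO06G01720, -1.32 ± 0.07) and the co-chaperone Cdc37 (NO14G02250, -1.06 ± 0.05). Among transcription factors 33 of 83 rose and 31 fell (48 and 14 with library totals alone, 64 adjusted over the list alone; camera adjusted p = 0.823; median -0.04, mean 0.10). The MYB-type genes MYB119 (NO18G02390, -2.69 ± 0.07), Mybl1 (NO21G02390, -1.42 ± 0.06) and myb (NO10G02720, +1.50 ± 0.08) had the smallest p-values.

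Proteasome, ubiquitin and autophagy genes rose in 108 and fell in 94 of 301 cases (175 and 48 with library totals alone; 201 adjusted over the list alone; camera adjusted p = 0.652). UBE2J1 (NO07G01230, -2.17 ± 0.05) and the protease SP2 (NO24G02090, -1.82 ± 0.06) were lower, and the ubiquitin ligase Rnf167 (NO15G00460) was higher, from 22.5 ± 4.02 to 187 ± 12.2 CPM. Redox and heat-shock genes fell in 106 and rose in 66 of 220 cases (173 adjusted over the list alone; camera adjusted p = 0.123). Their median of -0.13 became 0.18 with library totals alone. The chaperone clpB1 (NO16G01260) fell from 5666 ± 58.4 to 1801 ± 55.9 CPM. Thioredoxin trx1 (NO05G01860, -1.67 ± 0.06) and ilvA (NO05G02560, -1.58 ± 0.05, shared reads), a threonine dehydratase and not a redox protein, fell as well. For phosphate and sulfur uptake 16 of 40 rose and 14 fell (26 and 5 with library totals alone, 30 adjusted over the list alone; camera adjusted p = 0.44). The phosphate transporter PHT1-12 (NO16G01940) was at -0.86 ± 0.04 and the acid phosphatases PAP4 (NO12G01720) and PAP1 (NO07G00080, annotated as probably inactive) at +0.94 ± 0.06 and +1.26 ± 0.08. Both lists meant as controls for RNA quality and other sources matched other genes and serve no such purpose. The list for organelle-encoded and ribosomal RNA genes matched nuclear gene models by name (98 of 226 rose, 74 fell, or 146 and 44 with library totals alone, 172 adjusted over the list alone, camera adjusted p = 0.301). It was led by psbQ (NO16G02690, -4.10 ± 0.07), secA (NO10G02510, -2.30 ± 0.05) and clpB1. The list for transposable elements and viruses matched 8 tested genes (4 rose, 0 fell, 4 adjusted over the list alone, camera adjusted p = 0.211). It was led by the cellular genes tert (NO04G05270, +0.82 ± 0.10), LTV1 (NO08G02540, +0.66 ± 0.09, shared reads) and ZBED1 (NO14G02830, +0.45 ± 0.08, shared reads).

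The largest rises included 5 genes with no count in NR, each with shared reads. They were a Fe-S oxidoreductase (NO03G02420), kdsD (NO13G01870), thrc (NO01G01480), mepce (NO03G00940) and trmB (NO09G01460), at least 117, 70.7, 58.2, 49.3 and 44.4-fold higher in ND against a floor of 3 counts over the group. All of these except kdsD had an adjacent model whose counts summed with theirs to whole numbers, and these 4 are reported as uncertain. The sums were lower in ND, by log2 changes of -2.74 (NO03G02420), -0.33 (thrc), -0.17 (mepce) and -1.32 (trmB). Next came the kinase Stk16 (NO17G01240, shared reads, 0.55 ± 0.96 to 15.1 ± 2.95 CPM), NIA, and INPPL1 (NO19G02220, 2.05 ± 1.33 to 45.8 ± 1.24 CPM), an inositol phosphatase. The largest falls included 4 genes with no count in ND after rounding and with such a partner, namely an RST1 homologue (NO12G02120, at least 314-fold lower), LPAT4, ttc38 (NO19G01340, at least 134-fold lower) and trxA (NO11G02950, at least 62.6-fold lower). The sums with the partner changed by -0.55 (RST1 homologue), 1.00 (ttc38) and -0.36 (trxA). VPS1 (NO18G01620, shared reads) had 390 counts in NR and 3 in ND, a ratio of 193 with a counting interval of 65.6 to 941 (95%, Clopper-Pearson). Its NR libraries held 76.1, 17.6 and 4.72 CPM. The putative hydrolase SPCC777.06c (NO09G01940) had 154 counts in NR and 1 in ND, a ratio of 229 with an interval of 40.5 to 9100. FCPA followed, and then the RNA-binding protein RBP47C' (NO05G04970), which fell from 72.2 ± 6.15 to 0.96 ± 0.16 CPM. Among genes with whole counts, picked after seeing the values, the potassium channels TPKA (NO29G01700, +4.20 ± 0.10) and TPKC (NO29G01710, +4.17 ± 0.15) and the sodium/proton exchanger NHX8 (NO03G02820, 154 ± 6.20 to 1983 ± 33.2 CPM) stood beside NIA.

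By level, the most abundant transcript in NR was NO06G00260 (shared reads) at 10220 ± 264 TPM, without a description, followed by NO27G01660 at 9306 ± 419 TPM, also without one. Then came a short transcript model without annotation (shared reads) at 6306 ± 1720 TPM, whose length of 249 bp is close to the fragment size. LHCSR1 (NO02G05990) at 6261 ± 110 TPM and HSP23.2 (NO20G02140, shared reads) at 6227 ± 670 TPM came next. In ND the first was NO30G00310, with no description, at 10330 ± 424 TPM (+2.42 ± 0.05), followed by HSP81-1 (NO03G01460) at 7026 ± 200, HSP23.2 at 6826 ± 242, nrgA at 6270 ± 140 and hsp16 (NO20G02150, shared reads) at 6047 ± 143 TPM. The direction of HSP81-1 and HSP23.2 depended on the scaling, with HSP81-1 at -0.13 ± 0.04 under the trimmed mean scaling (adjusted p = 0.0045) and at 0.19 with library totals alone, and HSP23.2 at -0.30 ± 0.06 and 0.02. The change of hsp16 was -0.38 ± 0.05 and -0.07, and the latter was not called. The largest adjusted p among the genes chosen by the rule was that of HSP81-1.

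The authors' deposited table of their own comparison lists 2057 genes, 853 higher and 1204 lower in ND. Of these 2004 were tested here, and all 2004 had the same sign and an adjusted p under 0.05. The other 53 were removed by the filter on low counts. The authors' deposited table and the genes changed by at least 2 times here shared 1980 genes, and 64 genes called here were not in it. Across the 2004 genes, which are not independent replicates, the fold changes of that table and of this fit were correlated at r = 0.9993.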

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

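The tests of counting noise and of a one-way shift in this part were chosen only after the result was seen, as was the comparison of lengths itself. The deposited length of a gene is an average over its transcripts weighted by their estimated abundance. Among 3126 genes with more than 1 transcript and at least 50 counts in every library, it differed between ND and NR in 120 genes at an adjusted p of 0.05 (limma), 74 longer and 46 shorter in ND. A shift of at least 0.1 on the log2 scale was found in 62 of them, 33 longer and 29 shorter, a signal in data outside the main comparison. In 11 of the 62 there was no called change in level. In NRT2.1 (NO14G02450, shared reads) the mean length went from 3104 ± 15.2 to 2496 ± 5.1 bp (SD, n = 3; log2 shift -0.31, adjusted p = 6.81e-05). Other examples, picked after seeing the values, were abcG12 (NO30G00740, shared reads, 0.47 on the log2 scale, adjusted p = 0.000315) and OGG1 (NO11G00200, shared reads, -1.21, adjusted p = 0.0123).

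Counting noise in the transcript estimates would leave non-overlapping conditions in about 10% of genes, and 27.1% (847 of 3126) did not overlap, which argues against noise as the whole cause. A difference in fragment size or degradation that moves every length the same way is argued against by the directions, since 61.7% of the called shifts went the commoner way. A fragment-size effect that acts differently from gene to gene stays open, because the gap between length and effective length differed between the conditions in every library. A different use of transcripts without nitrogen may also explain part of the shifts, and no test here separates it from that effect.

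The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. In 1 of the 10 splits, the real one, the result was largest for the genes called (6645, highest other 0), the lists called (9, highest other 7), the pathways called (13, highest other 7) and the lengths called (120, highest other 1). Every other split mixed both conditions in each group, so the difference between conditions widened the spread within groups. The values of the other splits are therefore no measure of chance.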

How the results depend on the processing

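The alternatives chosen after seeing the data were thinning, library totals alone, whole counts only, matching on the displayed description, and pathways. The number of genes called stayed within 1.5 times of 6645 in all settings but the test against a change of 1.5 times, which called 2857 (1298 higher, 1559 lower). It was 6594 with RLE factors, 6763 with upper-quartile factors (57.6% higher), 5887 with DESeq2, 6527 after thinning, and 6271 to 6513 with each library left out. Directions depended on the scaling. Genes higher in ND numbered 5090 and lower 2031 with log2(FPKM + 1), 5059 and 2019 with log2(FPKM + 0.1), and 5075 and 2149 with library totals alone. Rises of at least 2 times numbered 1553, 1770 and 1658 in those settings, and falls of at least 2 times were 769 with log2(FPKM + 1). With library totals alone 5567 of the 6645 genes were also called and 85 had the opposite sign. RLE factors, upper-quartile factors and library totals alone changed only the scaling. The FPKM fits also changed the test, the filter and the genes tested, and why they differed was not tested further.

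The replicate block gave 6590 genes, 6539 of them shared with the fit without it. Deviations of same-numbered libraries correlated at 0.043, 0.037 and 0.033 over 5573 genes, above those of other numbers (at most -0.006), a hint from the data and too small to pair the cultures.

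Of 9 called lists, 2 were called with an estimated correlation and 22 lists were called by fry, which does not compare a list with other genes. With an estimated correlation the adjusted p was 0.278 for fatty acid synthesis, membrane glycerolipids, nitrogen uptake and storage carbohydrates, 0.45 for the Calvin cycle, 0.348 for ribosomal proteins and 0.46 for translation factors. With whole counts only, membrane glycerolipids had 0.127 and nitrogen uptake 0.104, and on the displayed description membrane glycerolipids had 0.0643. Calls were gained by the citrate and glyoxylate cycles with whole counts only (0.0149) and by redox and heat-shock proteins on the description (0.0404). All 9 lists were called with each library left out. Lists that were not called changed direction in some settings: triacylglycerol assembly on the description (0.837) and with fry (4.84e-06); lipases with the replicate block (0.989), with whole counts (0.949) and without NR replicate 1, NR replicate 2 or ND replicate 2 (0.963 to 0.998 over the 6 fits); lactate without NR replicate 3 (0.874 to 0.995 over the 6 fits); the proteasome with fry (0.614); transcription factors with whole counts (0.949), on the description (0.753) and with fry (0.45); and organelle genes on the description (0.753) and with fry (0.606). The cause was not tested.

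Of the values of 111 genes, those that the rule names and the largest changes with whole counts picked after seeing the values, 2061 kept direction and call. The reversed ones were heat-shock genes: HSP23.2 (NO20G02140) was at 0.10 in both FPKM fits and 0.02 with library totals alone, and HSP81-1 (NO03G01460) at 0.19 in all 3. Another 10 values kept their direction and lost the call, in HSP23.2, HSP81-1, hsp16, ADE17, LTV1 and ZBED1, and none of them with a library left out. Of the other genes named after their values were seen, DGAT1B, DGAT2D, GCN5, ATG1C, GLO1 and glod-4 lost the call against a change of 1.5 times. GLO1 also lost it in other settings, among them fits with a library left out. The sign of glod-4 reversed with library totals alone and in both FPKM fits. Depth limited genes near the floor: with 3 counts over a group as the floor, no level under 0.265 CPM in NR or 0.179 CPM in ND can be told from 0.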

Other observations

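The pathway comparison in this part was chosen only after the data were seen, as were the tests of reads shared with an adjacent model, of depth, of switched genes and of the scaling; the genes named here were picked after their values were seen. Of 90 KEGG pathways tested with camera, 5 were higher and 8 lower in ND at an adjusted p of 0.05, and 0 were called with an estimated correlation (smallest adjusted p 0.319). Members of the autophagy pathway were higher, with 24 of 35 rising and 3 falling (median 0.50, adjusted p = 0.00363, 0.42 with an estimated correlation). The median was 0.81 with library totals alone. They included ATG2 (NO14G00660, +1.32, shared reads), atg4b (NO14G00590, +1.40) and ATG1C (NO15G01130, +0.68), while Atg6 (NO11G01020) fell (-0.81). The phosphatase BSU1 (NO02G05020), also in this pathway, fell further, from 33.8 to 2.61 CPM (-3.73). The target-of-rapamycin kinase rose from 64.0 to 203 CPM (tor, NO16G00750, +1.67). Models neighbouring it by gene ID, MTOR (NO16G00740, +1.83), NO16G00760 (+1.51) and NO16G00770 (+1.19), rose too. All of these count as separate members of the pathway, and whether they are parts of the same gene was not tested. The pathway counts take no account of whether a member promotes or restrains autophagy. The wider list of proteasome, ubiquitin and autophagy genes did not shift as a set (camera adjusted p = 0.652).

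Ascorbate metabolism was lower, with 22 of 30 genes falling and 3 rising (median -0.56, adjusted p = 0.000816, 0.319 with an estimated correlation). The median was -0.24 with library totals alone, with 16 lower and 5 higher. The ascorbate peroxidases APXS (NO10G02430, 940 ± 58.8 to 359 ± 9.97 CPM, n = 3) and APX3 (NO08G00210, -1.64) fell, with GME-2 (NO16G00650, -1.88, shared reads), an epimerase of ascorbate synthesis. Alanine, aspartate and glutamate metabolism rose in 22 of 35 genes and fell in 9 (26 and 6 with library totals alone; adjusted p = 0.0379, 0.588 with an estimated correlation), including purF (NO03G03620, +0.98, shared reads) and CPS1 (NO05G03910, +0.97). The citrate cycle rose in 24 of 38 and fell in 8 (31 and 7 with library totals alone; adjusted p = 0.0124, 0.562 with an estimated correlation). Glycerolipid metabolism fell in 29 of 46 and rose in 10 (19 and 15 with library totals alone; adjusted p = 0.0496, 0.562 with an estimated correlation).

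A group of 15 genes had no count after rounding in one condition and at least 10 CPM in the other, 8 at 0 in NR and 7 in ND. The smallest bound was 44-fold, a size that the choice of genes at 10 CPM or more sets in advance, so it says nothing about depth. For 12 of the 15 (80%), the estimated counts and those of a model adjacent by gene ID summed to whole numbers in every library. The tolerance was 0.055. The same held for 16.4% of 8407 other genes at that level and 69.5% of 2073 other genes with fractional counts. For these 12, reads shared with the adjacent model are a candidate explanation, and a whole locus switched on or off is argued against by the sums, whose median absolute log2 change was 0.55. The 3 sums that changed at least 2 times went the opposite way to the gene (-2.74 for NO03G02420, -1.32 for NO09G01460 and 1.32 for NO06G01390). The 3 genes with no partner, kdsD (NO13G01870), NO07G00910 and NO17G01130, were at least 70.7-fold, 81.4-fold and 363-fold higher in ND, and whether a model elsewhere takes their reads could not be tested without a genome.

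Ribosome biogenesis genes (87 of 123 higher, 13 lower) and ribosomal protein genes (64 of 100 higher, 12 lower) were higher as lists in cells without nitrogen, the latter with adjusted p = 0.348 with an estimated correlation. The lowest median over both lists and 4 scalings was 0.329, but a scaling shifts all genes alike, so this tests nothing about their standing against other genes, and the amounts per cell stay open. Both medians lay at percentile 100 of 10000 lists matched on gene length and level, so these do not account for the difference from other genes. The highest matched medians were 0.34 for ribosome biogenesis and 0.12 for ribosomal proteins. Typical matched medians were 0.07 for ribosome biogenesis and -0.24 for ribosomal proteins, against 0.02 for all genes. Changes therefore went with length or level to some degree, and the lists that were lower in ND were not compared with matched lists. With whole counts only, the lower of the medians of the ribosome lists was 0.372, which argues against reads shared between paralogs. A response of the cells to nitrogen deprivation may explain the difference of these lists from other genes. This is a hypothesis found and tested on the same data, and transcript levels say nothing of ribosome numbers.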
